A study of Homo sapiens with 6 samples.

How the data were processed

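RNA sequencing of KYSE-150 cells was deposited as 1 table with a row for each of 50868 genes and, for each of 6 libraries, a count column and an FPKM column. Per the labels, total RNA was extracted with TRIzol, reverse transcribed, made into libraries with a VAHTS V6 kit and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.3b, edgeR and the hg38 genome build, with no role or order. The annotation release, the strand setting of counting, read trimming and filters are not given in the sources used here. Whether polyadenylated RNA was selected or ribosomal RNA removed is also not given.

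The deposited count columns held whole numbers that differed in total between libraries, with no normalization visible in the values. The deposited FPKM columns were, for each of 22289 genes with a count in at least 2 libraries, equal to the count divided by 1 length per gene and by the library's total count, with lengths within 0.079% of each other across libraries. The FPKM values therefore carry no correction for composition beyond the total, and counts were used for the main tests, with FPKM as an alternative. Without knowledge of strand use, reads of overlapping or antisense genes cannot be told apart, and close paralogs and pseudogenes could share reads.

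Columns were matched to libraries by the library titles. The groups were nc and siZNF514, with 3 libraries each, and no other per-sample column was present. Replicates were compared before averaging by a chi-square of their counts: pairs within a group had 8.02 to 10.4 per degree of freedom, so none agreed within sampling noise, and same-numbered pairs across groups had 49.5 to 52.2. On log2 CPM, the first principal component held 65.7% of the variance and separated the groups. Correlations across genes were at least 0.986 within groups and at most 0.960 between them. No batch or date is given in the labels, so none could be examined.

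Of the 50868 genes, 24873 had no count in any library. Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3) at its default settings (minimum count 10, minimum total 15), which left 14250 genes with at least 99.8% of each library's counts. Libraries were scaled by TMM factors of 0.954 to 1.05, and siZNF514 was compared with nc by the edgeR quasi-likelihood F test with 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The square root of the common dispersion was 0.123. The SE of a log2 fold change is its size divided by the square root of its F value. A second threshold required a change of at least 2-fold as well. CPM values are counts divided by the tested counts of a library times its TMM factor. The targeted gene also had an exact permutation test. At these depths 1 count is under 0.1 CPM, and genes at or near 0 were given as bounds against a floor of 3 counts over the group or as ratios with exact 95% binomial intervals, which cover counting error only since reads had no molecular identifiers.

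Before the data were examined, 30 gene lists were fixed, the design was set, and the alternatives were listed. The lists were compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Lists needed at least 5 measured members, which 27 had, and p-values were adjusted over those lists by Benjamini-Hochberg. The lists covered G1/S and DNA replication, G2/M and mitosis, cell cycle inhibitors and damage response genes, mesenchymal and matrix genes, epithelial junctions, squamous differentiation, integrins and focal adhesion, invasion proteases, interferon-stimulated genes, NF-kB and cytokines, unfolded protein and integrated stress responses, hypoxia, glycolysis, cholesterol, NRF2, MYC, ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, YAP/TEAD, TGF-beta, Wnt, EGFR and MAPK, apoptosis, histones, KRAB zinc fingers, 3 sets of other cell types and genes near ZNF514. Of their 869 symbols, 864 were in the table, 2 were matched by gene identifier and 3 were not matched.

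The genes named were fixed by a rule. It took 30 genes of proliferation, invasion and apoptosis whatever their result, and the 10 higher and 10 lower genes with the largest changes past the threshold at a mean FPKM of at least 1. It also took up to 4 members with the smallest p-value in each list, and the 5 genes with the smallest p-value in each direction. Some genes that the rule allows are not reported here. Any other gene is said to have been chosen after its values were seen.

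Alternatives were a fit with the replicate number as a block, each library left out in turn, DESeq2 size factors, total counts alone, no filter beyond a count above 0, a mean count of at least 50, the DESeq2 1.42.0 Wald test, and limma-trend on log2(FPKM + 0.1), with 1 and 0.01 as other pseudocounts and a mean FPKM of at least 0.5. For the lists, camera with an estimated correlation and fry were run. An offset for GC content and gene length (smooth trends from mgcv 1.9.3 over protein-coding genes) and a fit to protein-coding genes alone were added after seeing the data. GC content and length were known for 99.6% of tested genes. Alternatives planned for the case that only FPKM was deposited did not apply.

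Gene classes, GC content and 3' UTRs were taken from GENCODE release 29 on GRCh38. Of its identifiers, 50111 were in the table, and 94.9% of these had the same coordinates in both. For the search for short sequences, the longest annotated 3' UTR of each of 11744 tested genes was used (at least 50 bases). Log2 fold change was regressed on the presence of each of 15902 sequences of 7 bases found in at least 100 of these UTRs. The fits had cubic terms for UTR length and GC content and Bonferroni adjustment, using Biostrings 2.70.1.

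The steps were tested on simulated data. Counts were drawn for the 14250 tested genes at their real means, library sizes and dispersions, with 200 genes changed. The fit recovered 40.3% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 95.5% of those changed 4-fold. It called 11 of 14050 unchanged genes. These rates hold for that share of changed genes, far below the share called in the data. Of 26 simulated unchanged lists none was called, and 1 list of 30 genes raised 1.5-fold was called. In simulations of the sequence search over the 11744 UTRs, 5 of 5 sequences planted with an effect of -0.3 ranked first. None passed after shuffling. Smaller effects, such as those found in the data, were not planted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.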

Results

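Gene expression was measured by RNA sequencing in KYSE-150 cells, an established human oesophageal squamous cell carcinoma line grown in RPMI 1640 with 10% fetal bovine serum at 37 °C and 5% carbon dioxide. The libraries fell into 2 groups of 3, a control group titled nc, which the series text calls wild type, and a group titled si, named siZNF514 here, which the labels describe as a ZNF514 knockout by siZNF514. Whether the nc cells received a control siRNA is not given in the sources used here. The prefix si is usual for a short interfering RNA, which lowers a transcript without deleting its gene, and both words are given here only as the labels use them. The nc libraries held 12305102, 13696180 and 12175259 counts, and the siZNF514 libraries held 13262363, 13686077 and 14318909. Between 20842 and 21076 genes had a count in each nc library, against 19384 to 20216 in each siZNF514 library. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Every mean below is over the 3 libraries of a group, with the SD between them, and every log2 fold change is siZNF514 over nc with its standard error (SE).

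The first question was whether the targeted transcript was lower where the labels say it was targeted. ZNF514 (ENSG00000144026; GRCh38 chromosome 2, 95147330 to 95165413, minus strand) encodes a zinc finger protein. Its counts were 239, 273 and 261 in the nc libraries and 64, 82 and 63 in the siZNF514 libraries. The normalised level was 19.4 ± 1.048 CPM (counts scaled to the library size) in nc and 5.31 ± 0.871 CPM in siZNF514, which is 27.3% of the nc level. The deposited FPKM values were 1.78 ± 0.092 and 0.446 ± 0.0724. In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, ZNF514 fell, with a log2 fold change of -1.87 (SE 0.14, adjusted p = 5.77e-05). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. All 3 siZNF514 libraries lay below all 3 nc libraries, and transcript remained in each of them.

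The comparison of siZNF514 with nc, which addresses the part of ZNF514 in growth, migration and invasion of these cells, gave a broad change. Most measured mitotic genes rose and most interferon-stimulated genes fell. Most genes on the ribosomal protein, glycolysis, hypoxia and cholesterol lists also rose, and most on the histone and stress response lists fell, but as lists these lost their calls with an estimated correlation. The cyclin-dependent kinase inhibitors CDKN1A and CDKN1B rose, the mesenchymal transcription factor SNAI2 and the collagenase MMP1 fell, and the caveolar protein gene CAV1 fell (831 ± 45.2 to 174 ± 1.88 CPM). Of 14250 genes tested, 7212 (50.6%) passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 3629 of them higher and 3583 lower. A change of at least 2-fold was seen for 1323 of these, 296 higher and 1027 lower. The balance of directions depended on the scaling. With no scaling beyond total counts in place of TMM factors, 2493 genes past the threshold were higher and 4775 lower. The median log2 fold change of all genes then moved by -0.13. Fold changes are therefore relative to the bulk of genes, and the number of 2-fold changes fell to 673 among genes with a mean count of at least 50.

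**Figure D1:**
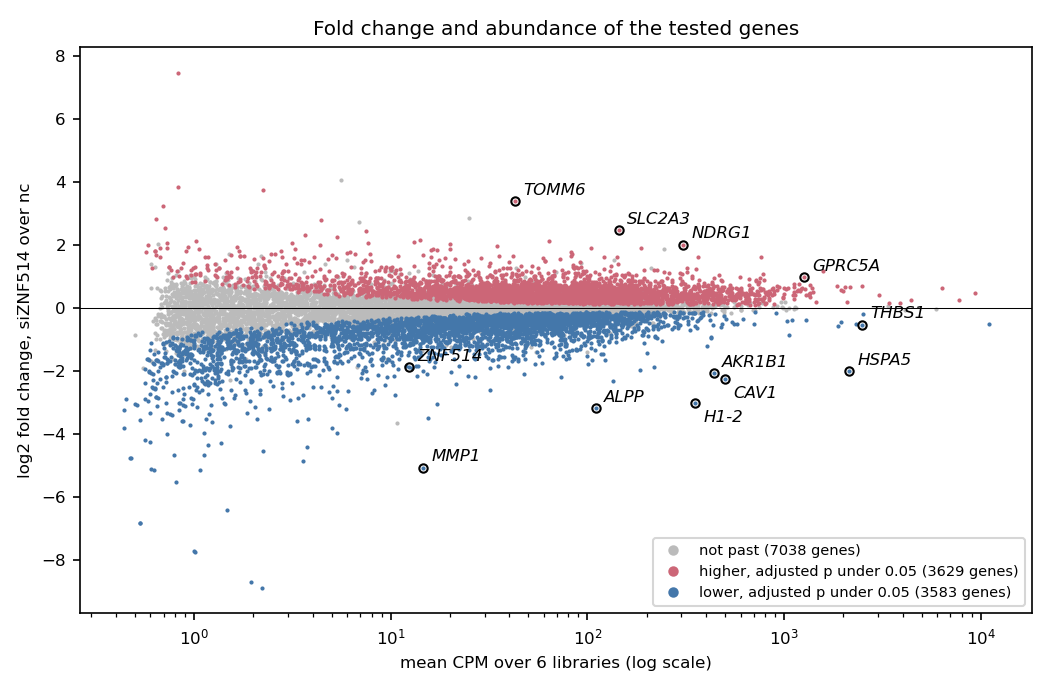
Log2 fold change of siZNF514 over nc (vertical axis) against the mean CPM over the 6 libraries (horizontal axis, log scale), 1 point per tested gene, red where higher and blue where lower at an adjusted p under 0.05, with 12 genes named in the text circled. The 3629 higher and 3583 lower genes cover the whole range of abundance, and 1027 lower genes against 296 higher ones changed at least 2-fold, MMP1 at -5.06 among them.

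Among the decreases with the smallest p-values, HSPA5, the main chaperone of the endoplasmic reticulum, fell from 3444 ± 28.9 to 852 ± 8.9 CPM (log2 fold change -2.02, SE 0.02). The linker histone gene H1-2 fell from 629 ± 2.33 to 77.9 ± 2.51 CPM (-3.01, SE 0.04). AKR1B1, an aldose reductase, fell from 706 ± 11.3 to 169 ± 5.09 CPM, and ALPP, a placental-type alkaline phosphatase whose reads close paralogs could share, fell from 198 ± 2.59 to 22 ± 1.56 CPM. The increases with the smallest p-values were in the hypoxia-responsive gene NDRG1 (122 ± 4.37 to 492 ± 4.95 CPM) and the glucose transporter gene SLC2A3 (44.4 ± 2.59 to 244.0 ± 4.13 CPM). Next were GPRC5A (852 ± 6.47 to 1666 ± 20.3 CPM), SINHCAF (78.6 ± 3.88 to 294.7 ± 6.97 CPM) and RRM2, a subunit of ribonucleotide reductase (189 ± 2.72 to 449.9 ± 8.86 CPM). Across these decreases and increases, adjusted p-values in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment ran from 1.98e-08 for HSPA5 to 2.78e-06 for RRM2.

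By size, the leading increases among genes with a mean FPKM of at least 1 were in TOMM6 (3.40, SE 0.40), SLC2A3 (2.46, SE 0.06), ANKRD37 (2.43, SE 0.23), MYLIP (2.24, SE 0.31), DEPP1 (2.16, SE 0.13), CCNG2 (2.14, SE 0.06), ARID3A (2.10, SE 0.12), INHBA (2.03, SE 0.15), NDRG1 (2.01, SE 0.04) and DGKH (1.95, SE 0.47). CCNG2 and DEPP1 are known targets of FOXO transcription factors, and INHBA encodes a subunit of activin. Some of these rested on uneven libraries: DGKH had counts of 248, 974 and 971 in siZNF514 against 158, 218 and 192 in nc, and TOMM6 had 30, 137 and 128 in nc against 952, 1033 and 1085. Among the decreases, LGALS7B (156 counts over the 3 nc libraries), the gastrin gene GAST (81) and the metallothionein gene MT1B (42) had no count in any siZNF514 library. Set against a floor of 3 counts over the siZNF514 group, these were at least 51.5-fold, 26.7-fold and 13.9-fold lower, for counting error only. LGALS7B and MT1B have near-identical copies that could share reads, so their values are uncertain. LINC02474 had 116 counts in nc and 1 in siZNF514, which is 0.87% of the nc level with an exact 95% interval of 0.0219% to 4.95%, its 1 count being in siZNF514 replicate 2. The others were MMP1 (-5.06, SE 0.15), H2BC8 (-4.41, SE 0.32), MMP3 (-3.80, SE 0.25), LINC01521 (-3.51, SE 0.56; -5.10 without siZNF514 replicate 3), H4C8 (-3.50, SE 0.11) and H2BC7 (-3.32, SE 0.41).

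Genes of the later cell cycle rose together. Of 37 measured genes of G2/M and mitosis, 34 rose, 1 fell and 2 did not pass, with a median log2 fold change of 0.65, and the counts were the same adjusted over the list alone. The mitotic kinase gene AURKA rose from 136 ± 1.67 to 313 ± 15.8 CPM, CCNA2 from 102 ± 3.93 to 219.6 ± 5.75 CPM, CCNB2 from 79.5 ± 4.18 to 181 ± 5.39 CPM, and CDK1 from 124 ± 4.65 to 208 ± 9.97 CPM. The member that fell was FOXM1 (-0.41, SE 0.12), and CENPA did not pass (0.35, SE 0.20), both chosen after their values were seen. MKI67, the proliferation marker, also did not pass (0.34, SE 0.38), with 1688, 1451 and 3840 counts in the siZNF514 libraries. Set against other genes, the list was higher in the camera test with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 27 lists (adjusted p = 5.82e-15), and also with an estimated correlation (adjusted p = 0.0478).

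Genes of G1/S and DNA replication moved both ways. Of 35 measured members, 7 rose, 10 fell and 18 did not pass, the same counts as adjusted over the list alone, and the list did not stand apart from other genes (median -0.01, camera with Benjamini-Hochberg adjustment, adjusted p = 0.905). RRM2 and CDK6 rose (log2 fold changes 1.25 and 0.96), while CDC6, which loads the replicative helicase, and PCNA, the sliding clamp of DNA polymerases, fell (-1.07 and -0.93). CCND1, CCNE1, CDK2 and CDK4 did not pass, with log2 fold changes of 0.03, 0.02, 0.04 and -0.08. Without siZNF514 replicate 1, CDK2 passed at 0.24.

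Among cell cycle inhibitors and damage response genes, 12 of 29 measured members rose, 6 fell and 11 did not pass (13 and 6 adjusted over the list alone), and the list as a whole did not pass (camera with Benjamini-Hochberg adjustment, adjusted p = 0.170). CDKN1A rose from 37.5 ± 3.66 to 128 ± 3.26 CPM, and CDKN1B, another inhibitor of cyclin-dependent kinases, rose from 52.9 ± 1.29 to 126 ± 5.21 CPM. BBC3 (0.98) rose as well, while BAX, which promotes apoptosis, fell (-0.46, SE 0.06). Among 32 measured apoptosis regulators, 11 rose, 5 fell and 16 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.115). Those that rose included MCL1 (0.96), BIRC3 (1.11) and PMAIP1 (0.79). BCL2 (-1.07) fell with BAX, and CASP2 (-0.82), CASP8 (-0.82) and FADD (-0.37), chosen after their values were seen, fell too.

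**Figure D2:**
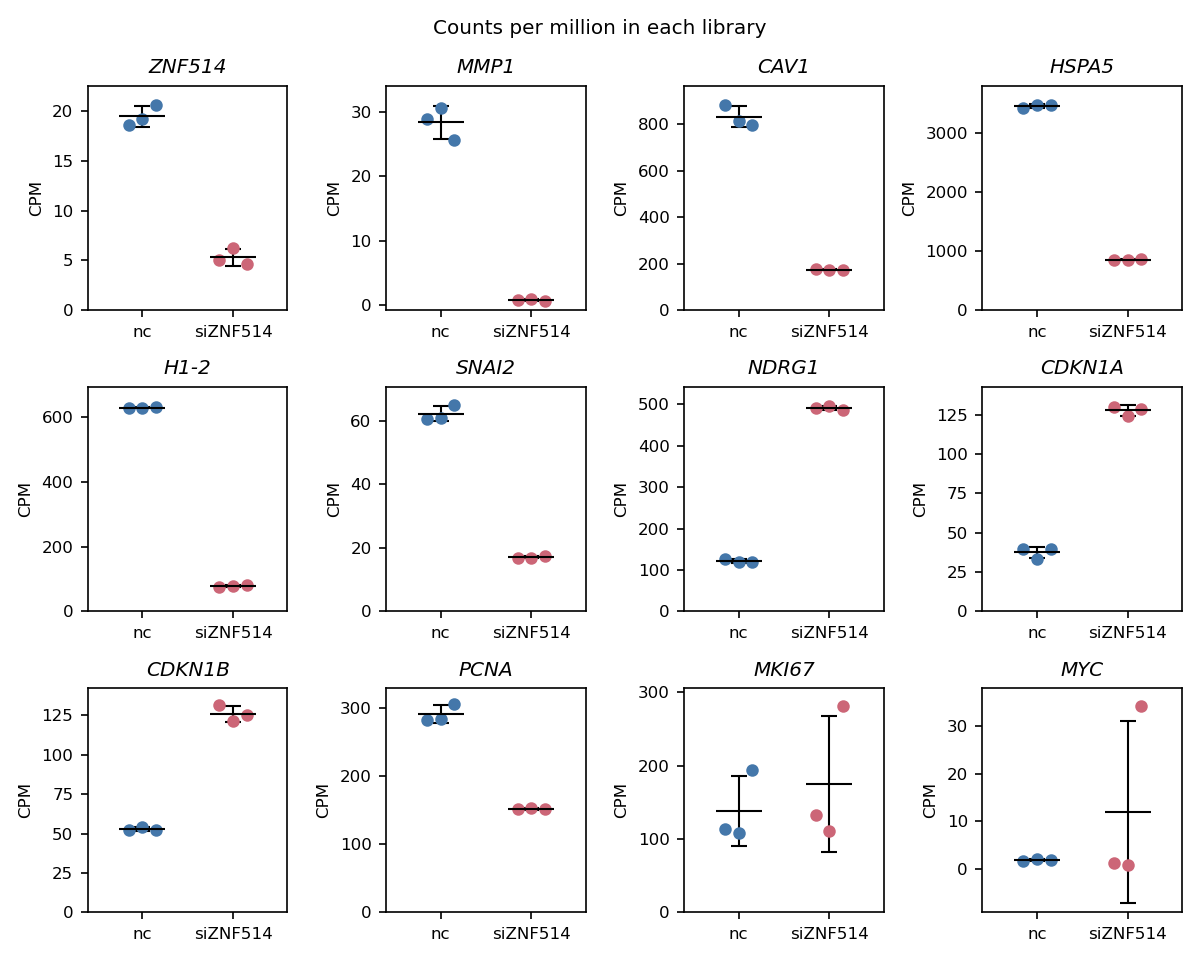
CPM (vertical axis, 1 scale per gene) of 12 genes in each of the 3 nc (blue) and 3 siZNF514 (red) libraries, with the group mean as a bar and the SD as whiskers. ZNF514, MMP1, CAV1, HSPA5, H1-2, SNAI2 and PCNA were lower in all 3 siZNF514 libraries, NDRG1, CDKN1A and CDKN1B were higher in all 3, and the siZNF514 mean of MYC rests on 1 library.

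Genes tied to migration and invasion did not move as 1 group. SNAI2, a repressor of epithelial genes, fell from 62.1 ± 2.32 to 17 ± 0.334 CPM (-1.87, SE 0.06), ZEB1 fell at a low level of 1.66 ± 0.29 CPM in nc (-0.81, SE 0.26; not past without siZNF514 replicate 3, at -0.65), and FN1 fell (-0.36, SE 0.08). VIM (0.06, SE 0.16), TWIST1 (0.48, SE 0.23) and CDH1 (-0.23, SE 0.21) did not pass. TWIST1 passed at 0.68 without siZNF514 replicate 1. CDH2, SNAI1 and MMP9 had too few counts to test. Of 19 measured mesenchymal and extracellular matrix genes, 9 fell, 4 rose and 6 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.202). Those that fell included the actin-binding protein gene TAGLN (-3.06, SE 0.19), TNC (-1.08, SE 0.05) and THBS1 (-0.53, SE 0.03). COL1A1 (0.75) and MMP2 (0.27) rose, as did COL4A2 (0.34) and LOXL2 (0.50), the last 2 chosen after their values were seen. COL1A1 had 197, 178 and 312 counts in the siZNF514 libraries, was 0.50 without siZNF514 replicate 3 and did not pass without nc replicate 3, and MMP2 no longer passed with total counts alone (0.15) or without nc replicate 1.

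Among 23 measured proteases of invasion and their inhibitors, 7 rose, 7 fell and 9 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.905). The neighbouring stromelysin and collagenase genes MMP3 and MMP1 fell, MMP1 from 28.3 ± 2.52 to 0.839 ± 0.0959 CPM and MMP3 from 9.34 ± 1.16 to 0.662 ± 0.242 CPM. The urokinase receptor gene PLAUR (1.28), ADAM9 (0.84) and the membrane-bound protease gene MMP14 (0.40, SE 0.04) rose. Of 29 measured genes of integrins, laminins and focal adhesion, 15 rose, 3 fell and 11 did not pass (16 and 3 adjusted over the list alone), among them LAMC1 (0.72), ITGB5 (0.61) and ACTN4 (0.47). CAV1 fell (-2.25, SE 0.05), as did ITGAV (-0.40) and PARVA (-0.32), chosen after their values were seen, while ITGB1 did not pass (0.08, SE 0.05; past at 0.14 without siZNF514 replicate 3). This list was higher in the camera test with Benjamini-Hochberg adjustment (adjusted p = 0.0148), but not with an estimated correlation (adjusted p = 0.112), with total counts alone (adjusted p = 0.130), with a mean count of at least 50 or in limma-trend on FPKM.

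Epithelial junction genes split, with 11 of 29 measured members higher, 7 lower and 11 not past, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.710). The membrane protease gene ST14 rose (0.60), and the desmosomal cadherin genes DSG2 (-0.55) and DSC2 (-0.97) fell. Of 18 measured genes of squamous and keratinocyte differentiation, 8 fell, 1 rose and 9 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0557). KRT6A (-2.16, SE 0.18), KRT6B (-4.27, SE 0.51) and KRT14 (-1.23, SE 0.14), keratins of stressed and basal squamous cells, fell, and KRT15, another basal keratin, rose (1.12, SE 0.09). KRT6A and KRT6B are close paralogs, and KRT6B had 1, 3 and 1 counts in siZNF514, so its fold is uncertain (-4.94 without siZNF514 replicate 2). Without nc replicate 1, the list passed (adjusted p = 0.0424).

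Interferon-stimulated genes fell together. Of 34 measured members, 27 fell, 1 rose and 6 did not pass, with a median log2 fold change of -0.88, and the counts were the same adjusted over the list alone. IFIT2 fell from 173 ± 5.95 to 62.3 ± 2.41 CPM, IFIT3 from 118 ± 1.6 to 41.5 ± 2.85 CPM, IFI6 from 55.2 ± 4.73 to 9.0 ± 1.22 CPM, and OAS3, a sensor of double-stranded RNA, from 297 ± 10.9 to 153 ± 3.91 CPM. The member that rose was IRF1 (0.31, SE 0.06), chosen after its values were seen. The list was lower in the camera test with Benjamini-Hochberg adjustment (adjusted p = 2.09e-10) and with an estimated correlation (adjusted p = 0.0478). NF-kB targets and inflammatory cytokines moved both ways, with 11 of 23 higher, 5 lower and 7 not past (12 and 7 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, adjusted p = 0.194). NFKB2 (0.68), BIRC3 (1.11) and IL1A (0.49) rose, while the secreted factor genes IL6 (-1.28), CXCL2 (-1.44), IL11 (-1.39), CCL20 (-1.17) and CCL2 (-1.12) fell, all but IL6 chosen after their values were seen.

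Of 33 measured genes of the unfolded protein and integrated stress responses, 21 fell, 5 rose and 7 did not pass (22 and 6 adjusted over the list alone), with a median of -0.52. HSPA5, PDIA4 (-0.63), a disulfide isomerase of the endoplasmic reticulum, and SLC7A5 (-0.58), an amino acid transporter, fell. DDIT4, an inhibitor of mTORC1 signalling, rose from 506 ± 11.1 to 1059 ± 23.4 CPM, and VLDLR (1.87), PHGDH (0.44), ASNS (0.42) and ATF4 (0.38), chosen after their values were seen, rose too. The list was lower in the camera test with Benjamini-Hochberg adjustment (adjusted p = 0.00675), a call lost with an estimated correlation (adjusted p = 0.0861).

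Hypoxia-responsive and glycolytic genes rose. Of 24 measured hypoxia targets, 16 rose, 1 fell and 7 did not pass, the same counts as adjusted over the list alone, with a median of 0.65. NDRG1, SLC2A3, the transcriptional repressor gene BHLHE40 (1.63, SE 0.07) and the histone demethylase gene KDM3A (1.34, SE 0.09) rose, while VEGFA, chosen after its values were seen, fell (-0.81, SE 0.12). Of 20 glycolysis genes, 15 rose, 2 fell and 3 did not pass (16 and 2 adjusted over the list alone), with a median of 0.61. ENO1 rose from 1669 ± 12.4 to 2637 ± 46.6 CPM, PGK1 from 837 ± 27.9 to 1411 ± 19.2 CPM, PGAM1 from 223 ± 0.934 to 378 ± 4.96 CPM, and ENO2 from 23.1 ± 0.907 to 55.0 ± 2.43 CPM. HK1 (-0.54) and LDHA (-0.35), both chosen after their values were seen, fell. The camera test with Benjamini-Hochberg adjustment called both lists higher (adjusted p = 3.97e-05 for hypoxia targets and 7.2e-06 for glycolysis), and both calls were lost with an estimated correlation (adjusted p = 0.0597 and adjusted p = 0.0557).

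Genes of cholesterol synthesis and uptake rose, with 15 of 22 measured members higher, 3 lower and 4 not past (16 and 3 adjusted over the list alone) and a median of 0.56. HMGCS1 rose from 378 ± 8.7 to 1155 ± 89.1 CPM, MSMO1 from 179 ± 3.51 to 553 ± 32.3 CPM, and FDFT1 from 173 ± 5.5 to 336 ± 4.89 CPM. TM7SF2 (-0.96) and PMVK (-0.76), chosen after their values were seen, were among those that fell. The list was higher in the camera test with Benjamini-Hochberg adjustment (adjusted p = 0.000184), but not with an estimated correlation (adjusted p = 0.0861). NRF2 targets moved both ways, with 8 of 24 higher, 6 lower and 10 not past (8 and 7 adjusted over the list alone; camera with Benjamini-Hochberg adjustment, adjusted p = 0.905). The redox genes UGDH (-0.87), GCLM (-0.60) and ABCC3 (-0.85) fell, and TXN (0.50) rose.

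Cytoplasmic ribosomal protein genes rose almost as a block: 45 of 49 rose, none fell, and RPL11, RPL14, RPS12 and RPS27, named after their values were seen, did not pass (0.03, 0.21, 0.16 and -0.12), the same counts as adjusted over the list alone. The median was 0.50, and examples were RPL5 (0.63), RPSA (0.63), RPS9 (0.56) and RPL23 (0.77). Many of these genes have processed pseudogenes that could share reads. Of 34 nuclear genes of oxidative phosphorylation, 27 rose, 1 fell and 6 did not pass (29 and 1 adjusted over the list alone), with a median of 0.50. COX8A (0.84), UQCRC2 (0.74), SDHA (0.70) and ATP5F1C (0.46) rose, and NDUFS1, chosen after its values were seen, fell (-0.17). The camera test with Benjamini-Hochberg adjustment called both lists higher (adjusted p = 4.08e-15 and 2.0e-08), and both calls were lost with an estimated correlation (adjusted p = 0.147 and adjusted p = 0.0861).

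The mitochondrially encoded genes went the other way. Of 13, 8 fell, 1 rose and 4 did not pass (9 and 1 adjusted over the list alone), with a median of -0.30. MT-ND1 fell from 1363 ± 40 to 752 ± 12.3 CPM, and MT-CO1 (-0.51), MT-ND2 (-0.46) and MT-ND5 (-0.39) fell as well, while MT-ND3, chosen after its values were seen, rose (0.83). Genes of the mitochondrial chromosome took 4.84% to 4.93% of counts in the nc libraries and 3.89% to 3.98% in the siZNF514 libraries. The camera call with Benjamini-Hochberg adjustment (adjusted p = 0.00426) was lost with an estimated correlation (adjusted p = 0.319) and after the GC and length offset chosen after seeing the data (list: Mitochondrially encoded genes, median -0.16, adjusted p = 0.0751).

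MYC had 21, 29 and 23 counts in the nc libraries and 15, 11 and 465 in the siZNF514 libraries, so its value (2.72, SE 1.34, not past) rested on siZNF514 replicate 3, without which it was -0.84 and also not past. Of 30 MYC targets in ribosome biogenesis, 7 rose, 8 fell and 15 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.905). ODC1 (1.12) and NPM1 (0.41) rose, and the transferrin receptor gene TFRC (-1.21) and GRWD1 (-0.63) fell.

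Signalling targets were divided. Of 25 YAP/TEAD targets, 14 rose, 2 fell and 9 did not pass, the same counts as adjusted over the list alone. NUAK2 (1.02), AMOTL1 (0.43) and PTPN14 (0.39) rose, and AJUBA fell from 291 ± 13.8 to 108 ± 1.5 CPM, as did TGFB2 (-0.42), chosen after its values were seen. The list was higher in the camera test with Benjamini-Hochberg adjustment (adjusted p = 0.0148), but not with an estimated correlation (adjusted p = 0.167), with a mean count of at least 50 or in limma-trend on FPKM. Of 23 TGF-beta targets, 8 rose, 8 fell and 7 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.644), with JUNB (0.86), KLF10 (0.79) and INHBA higher. Of 9 measured Wnt targets, 3 rose and 2 fell, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.905). The Wnt inhibitor gene DKK1 fell from 293 ± 4.32 to 75.4 ± 4.17 CPM, and TCF7 (-1.11), chosen after its values were seen, fell, while CCND2 (0.97), NKD1 (1.29) and SOX9 (0.31) rose. Of 26 EGFR ligands and MAPK feedback genes, 10 rose, 9 fell and 7 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.941). EGFR itself fell from 577 ± 36.9 to 379 ± 31.8 CPM and the immediate early gene EGR1 fell (-1.63), while DUSP5 (0.77), ETV4 (0.65) and IER3 (0.46) rose.

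Replication-dependent histone genes fell: 13 of 18 measured members fell, none rose, and 5 did not pass (13 lower and 1 higher adjusted over the list alone), with a median of -1.38. Besides H1-2 and H4C8, H2BC5 fell from 40.3 ± 3.95 to 13.1 ± 0.991 CPM and H2AC6 from 56.9 ± 2.45 to 30.2 ± 1.13 CPM. The members that did not pass, chosen after their values were seen, were H2AC11 (0.12), H2BC11 (0.31), H3C8 (0.26), H2BC4 (-0.27) and H2BC9 (-0.38). Copies of these genes are nearly identical and most of their transcripts lack a poly(A) tail, so single members are uncertain. The list was lower in the camera test with Benjamini-Hochberg adjustment (adjusted p = 3.35e-05), a call lost with an estimated correlation (adjusted p = 0.0564).

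Of 63 measured KRAB zinc finger genes and their cofactors, the family to which many zinc finger repressors belong, 17 fell, 8 rose and 38 did not pass, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.170). ZNF189 (-1.71) and ZNF37A (-1.06) fell, and of the heterochromatin protein genes CBX5 fell (-0.58) and CBX1 rose (0.48). Of 10 measured genes near ZNF514 on chromosome 2, 4 rose and 2 fell, the same counts as adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.905). STARD7 (-1.19) and TMEM127 (-0.92) fell, and NCAPH (0.35), SNRNP200 (0.23) and, chosen after their values were seen, MRPS5 (0.30) and PROM2 (0.25) rose. Markers of other cell types were too few to test as lists. For fibroblasts 2 were measured, COL1A1 and LUM (-0.06, SE 0.68); for endothelial and blood cells 3, CD68 (-0.23), CDH5 (-0.55) and VWF (-0.71), none past; and for liver, kidney and nerve 4, of which SERPINA1 fell (-1.55) and MAP2, SYP and TUBB3 did not pass (-0.49, -0.33 and 1.15). Without siZNF514 replicate 3, LUM (-1.38) and TUBB3 (1.59) passed. CD68 passed without nc replicate 3 (-0.29) and MAP2 without nc replicate 2 (-0.64).

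**Figure D3:**
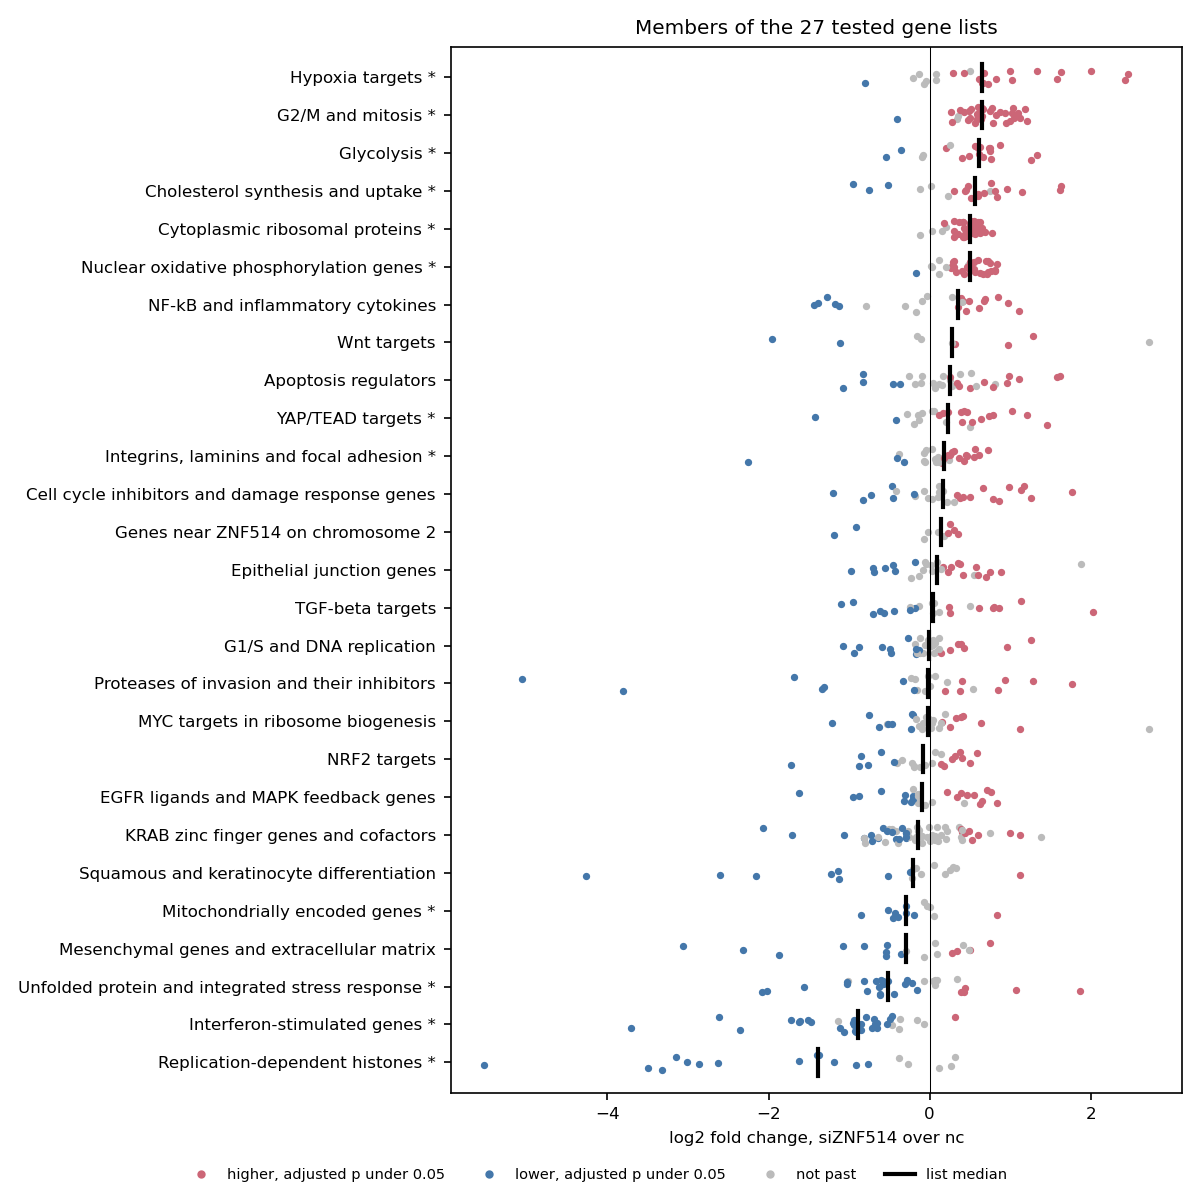
Log2 fold change of siZNF514 over nc (horizontal axis) for each measured member of the 27 tested gene lists, 1 point per gene, red where higher, blue where lower and grey where not past an adjusted p of 0.05, with the list median as a black bar and an asterisk on the 12 lists past the camera test with a preset correlation. Of those, 8 were higher and 4 lower, and only the mitotic and interferon-stimulated lists also passed with an estimated correlation.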

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

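The correction for GC content and gene length and the fit to protein-coding genes alone were chosen only after the data were seen, and the other alternatives were planned. ZNF514 was lower and past the threshold under all 17 alternatives run for it, with log2 fold changes from -2.003 to -0.94, the smallest size with a pseudocount of 1 on FPKM, which by construction shrinks low genes. The number of genes past the threshold stayed within 1.5 times of 7212 in all 17 (6260 to 7427; 6310 to 6563 with 1 library left out). The number changed at least 2-fold was 1310 to 1371 with 1 library left out, and fell to 673 with a mean count of at least 50, which tests fewer low genes, and to 373 with limma-trend on log2(FPKM + 1), which shrinks low genes. The number of lists past the threshold was 12 to 13 with 1 library left out, 2 with camera and an estimated correlation, which allows for genes of a list moving together, and 24 with fry, which does not compare a list with other genes. Under fry, Wnt targets (median 0.28) and genes near ZNF514 (median 0.14) were called lower, against higher but not past in the main test, and the cause was not tested. The replicate numbers gave no sign of pairing: correlations of deviations between libraries of the same number were 0.01, 0.04 and -0.04, and 2 of 6 libraries were closest to their own number. With the number as a replicate block, 6640 genes, 1275 genes at 2-fold and 12 lists passed, and no list call changed. Total counts alone gave 2493 higher and 4775 lower genes, and limma-trend on log2(FPKM + 0.1), which carries the same scaling, gave 2477 and 4122 (shifts of all genes of -0.13 and -0.12). Over 153 named genes, 2531 of 2572 values kept their side of the threshold, 24 lost and 17 gained a call, and 35 changed sign, none of them with a call. Small changes can be missed: with 200 of 14250 genes changed in the simulation, the fit found 40.3% of 1.5-fold changes. Recovery with as many changed genes as the 7212 called here was not simulated.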

Other observations

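The tests of TATCCAAA that follow its discovery (graded response, genes without a match, and matches in coding sequence) were chosen only after the result was seen, as was the correction for GC content and length as an alternative fit. The other tests were written down before, with some departures. The small nucleolar RNA test was written for a median and run on summed CPM, and the olfactory receptor test was limited to genes with at most 3 counts per library. The rule for small nucleolar RNA was changed after its value was seen, so that genes averaging under 10 counts per library leave it undecided. By the rule as first written, that value would have counted against its explanation. The S phase rule was also changed later, so that a list with members called in both directions leaves it undecided. By the rule as first written, the list's median would have counted against fewer cells in S phase.

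Gene classes outside protein-coding genes moved in different directions. Of 1206 tested long non-coding genes, 356 fell and 124 rose, and their share of all counts was 0.946% ± 0.00749 in nc and 0.769% ± 0.00466 in siZNF514 (SD over 3 libraries). Of 958 tested pseudogenes, 275 rose and 109 fell, with a share of 3.69% ± 0.0344 in nc and 4.62% ± 0.0924 in siZNF514. Among them, 63 of 96 ribosomal protein pseudogenes rose and 3 fell, with a median log2 fold change of 0.54 beside 0.50 for the ribosomal protein genes themselves, whose reads they could not be separated from here. Histone genes outside the fixed list, chosen after their values were seen, included members that rose: the linker histone gene H1-10 (1.11, SE 0.03) and the variant gene H2AZ1 (0.71, SE 0.08), whose transcripts are polyadenylated. H2AC19 (-1.91, SE 0.09) and H3C6 (-1.81, SE 0.20) fell.

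The low side of the change carried a short sequence of the targeted transcript. Of 15902 sequences of 7 bases, the strongest association with a lower log2 fold change when present in the 3' UTR was that of ATCCAAA (1508 genes, effect -0.17, Bonferroni-adjusted p = 2.77e-15), and the next was TATCCAA (1044 genes, effect -0.19, Bonferroni-adjusted p = 1.08e-14). Both lie in TATCCAAA, found once in each of 4 annotated ZNF514 transcripts, at chromosome 2, 95152753 to 95152760 (GRCh38, minus strand). In the 3011-base transcript it lies in the coding sequence of exon 4, within GGGCCTTCTAGTATCCAAA. In all, 13 sequences passed in this direction, 10 of them found in ZNF514, whose transcripts hold 30.4% of the sequences tested. In the other direction 7 passed, 4 of them found in ZNF514.

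A candidate explanation is a short interfering RNA aimed at this stretch of ZNF514, whose seed, the bases that also bind partly matched transcripts, would pair with TATCCAAA in other genes. The median log2 fold change was -0.24 (bootstrap SE 0.03) in 444 genes with TATCCAAA in the 3' UTR, -0.09 in 600 with TATCCAA only, -0.08 in 941 with ATCCAAA but not TATCCAA, -0.05 in 1216 with ATCCAA only and 0.03 in 8543 with none, a graded order. Of the 444, 183 fell and 63 rose. These are the genes in which the sequence was found, so the low median of the longest match restates that choice in part. A comparison of TATCCAA with other orders of its bases was dropped because that choice fixed its outcome, so base composition was not excluded. Genes with TATCCAAA that fell included CAV1 (-2.25), DKK1 (-1.96), EGR1 (-1.63), STARD7 (-1.19), ZNF37A (-1.06) and DSC2 (-0.97) and, chosen after their values were seen, FGF2 (-2.19) and the interferon-stimulated gene EIF2AK2 (-0.94); PTPN14, which also holds it, rose (0.39). In 186 genes with TATCCAAA in the coding sequence and no match in the 3' UTR, a part not used to find it, the median was -0.09 (bootstrap SE 0.05), against 0.04 in 6310 genes with no ATCCAA in either part. The sequence of the siRNA is not given in the sources used here, and an endogenous microRNA with this seed was not tested.

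Direct seed matches were argued against as the whole cause of the broad change. Among genes with no ATCCAA in the 3' UTR, 52.6% (4490 of 8543) still passed the threshold, 2496 higher and 1994 lower. The excess of lower genes with a match over the rate without one was 283, or 9.35% of the 3024 lower genes with a UTR. Interferon-stimulated genes without a match had a median of -0.85 (18 of 23 fell), and mitotic genes without one had a median of 0.64 (30 of 32 rose), so neither change rests on members with a match. What remains open is whether the rest followed from the loss of ZNF514 itself, from indirect effects of genes hit through the seed, from delivery of an siRNA as such, or from differences between the cultures. Only 1 siRNA group is present, and whether nc received a control siRNA is not given in the sources used here. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split was the 1 split with as many genes past the threshold (7212, highest other 1), the 1 with as many genes at 2-fold (1323, highest other 1) and the 1 with as many lists (12), but all 9 other splits gave lists as well, from 4 to 10.

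The lower long non-coding genes had a median log2 fold change of -0.27. The GC content and gene length trend was argued against, since the median after its removal was -0.26 (bootstrap SE 0.03). Low abundance rather than class stays a possible explanation: protein-coding genes matched on mean CPM had a median of -0.37 over 1000 draws (-0.45 to -0.29), and over all tested genes the median fell from 0.18 above 100 CPM to -0.50 below 1 CPM. Fewer background reads in siZNF514 cannot be told apart from this, because 370 olfactory receptor genes held only 5.67 ± 4.51 counts per nc library and 4 ± 4.36 per siZNF514 library (log2 ratio -0.57, SE 1.42). A biological loss of such transcripts with siZNF514 stays open as untested.

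The replication-dependent histone genes had a median of -1.38. Poorer capture of RNA without a poly(A) tail cannot be told apart: small nucleolar and Cajal body RNA genes had a summed log2 ratio of 0.15 (SE 0.14), but 28 genes held only 85.3 ± 4.51 counts per nc library and 94 ± 8.66 per siZNF514 library, and 5 were tested. The rise of the polyadenylated H1-10 and H2AZ1 goes with it. Fewer cells in S phase cannot be told apart either, since 7 genes of the G1/S and DNA replication list rose and 10 fell. The list's median was -0.0128 (bootstrap SE 0.0531), above the limit of -0.691 that the rule as first written set. How far this median moves with the share of cells in S phase was not measured, so that limit decides nothing. Reads shared between histone copies were not tested. A biological change in histone transcription or processing with siZNF514 may account for the pattern, as a hypothesis only.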
